A study of Musa acuminata AAA Group with 4 samples.

How the data were processed

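Polyadenylated RNA from leaves and roots of Cavendish banana seedlings, a triploid dessert banana, was sequenced after 60 days in complete Hoagland nutrient solution or in a solution low in potassium. Per the labels' protocols, RNA was extracted with a CTAB method, treated with DNase, enriched on oligo(dT) beads, fragmented and copied with random hexamers before adaptor ligation and PCR. These steps as described do not mark the strand, so reads from a gene and an antisense partner cannot be told apart. The labels give 4 samples, 1 for each combination of tissue and potassium supply, and nothing says whether a sample pooled several plants.

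The authors deposited 1 table per tissue and a short table on potassium transport. Per the file headers, each tissue table gives for every gene its length, an expression value and an FPKM value per sample, a log2 ratio of low over normal potassium, a p-value, an FDR and annotation. The deposited expression values are estimated counts of fragments and are not all whole: between 33.8% and 38.1% of the values of a sample differed from a whole number by more than 0.001, as happens where fragments are shared out between similar genes or transcripts, so the values of gene families are uncertain. The deposited FPKM values, scaled by the authors for gene length and library total, follow the counts for most genes and are 0.001 wherever the deposited count is 0. The deposited log2 ratio was equal to the log2 of the ratio of the FPKM columns in every row to the digits given, so genes at 0 carry a very large ratio that depends on the 0.001. The aligner, the counting program, the genome build and the test behind the deposited p-value and FDR are not given in the sources used here. In the authors' deposited tables the largest FDR was 0.000995 in leaf and 0.000987 in root and the smallest absolute log2 ratio was 1.0, so the tables hold genes past an FDR limit of 0.001 and a log2 limit of 1. The header of the potassium table names no unit, but its values matched the FPKM columns within 0.006 for all 10 genes it shares with the leaf table and all 22 it shares with the root table. Gene names are the protein descriptions of the deposited database matches. They matched an informative protein name for 967 of the 1183 leaf genes and 3711 of the 4747 root genes. The gene table supplied for names belongs to another assembly, so no coordinates were taken from it.

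Sequencing depth was recovered from the deposited values. For most genes of a sample the ratio of count to FPKM follows a straight line in gene length whose slope is the number of fragments assigned to genes. The line was fitted to genes with a count above 100 and an FPKM above 5, dropping genes more than 1% off it. In normal potassium 352 of 371 such genes in leaf and 2131 of 2199 in root lay within 1% of it. In low potassium all 508 in leaf and all 1772 in root did. For genes off the line, the ratio of FPKM values differs from that of the counts. The line gave 4302808 fragments in normal-potassium leaf, 4203693 in low-potassium leaf, 4555265 in normal-potassium root and 4312711 in low-potassium root. Gene lengths are multiples of 3 in 95.3% of leaf and 95.4% of root genes and are coding lengths. The fold between 2 samples is the ratio of their FPKM values. Its 95% interval is the exact (Clopper-Pearson) binomial interval of the low-potassium count given the sum of both counts, rounded to whole numbers. Where a potassium table gene is not in a tissue table, its counts were computed from FPKM, length and depth. Where 1 count was 0, the fold was computed against a floor of 3 counts in that library and is a lower bound that takes the other count as exact. All intervals and floors cover counting error only, and PCR copies are not independent molecules.

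With 1 library per tissue and potassium supply there is no replicate check, no test within a tissue was possible and no p-value is given. A test of an effect shared by both tissues was not run. A gene is called higher or lower here when it is in the authors' deposited table of that tissue, which compares 2 libraries and not 2 conditions. Before the data were examined, 28 gene lists were fixed by words in the protein descriptions. They cover potassium and other cation transport, proton pumps, calcium signalling, nutrient, water, sugar and ABC transport, photosynthesis, redox enzymes, phenylpropanoids, cell wall, hormones, transcription factor families, receptor-like kinases, defence, heat shock, ribosomes, cell division and cytochrome P450 enzymes. The photosynthesis list also serves as a marker of green tissue in roots. For each list of 3 or more listed genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from the same table and matched on mean FPKM in 10 bins. The match was repeated with coding length and mean FPKM in 5 bins each. These percentiles describe the libraries and are not p-values, and since unlisted genes were not analysed here they compare a list only with other listed genes. The naming rule, also fixed beforehand, took every gene of the potassium table. Per tissue it took the 8 genes with the largest ratio in each direction among named genes detected in both libraries with a mean FPKM at or above the table median, and the 3 most abundant named genes per direction. It also took up to 2 most abundant members per list in the list's main direction, and the 4 most changed genes shared by the tissues in the same and in opposite directions. The text leaves out some genes from the end of these parts. A lower limit on the number of genes the authors tested was computed as the largest product of FDR/p and rank in a table, which holds if the FDR follows Benjamini and Hochberg. It was 21486 in leaf and 30160 in root.

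Alternatives were an absolute log2 ratio of 2, a filter at the table's median FPKM, a pseudocount of 1, leaving out genes at 0, the 3-count floor, scaling to the total of unlisted genes, and leaving out genes with a count that is not whole. Scaling by TMM or by median ratios needs all genes and was not run. The interval and list procedures were run on simulated counts drawn from the real means and depths with 200 changed genes. These counts held counting error only, which is what the intervals assume. A list of raised genes lay at percentile 100, and a list of unchanged genes at 18.3 in leaf and 56.8 in root. Most simulated genes were unchanged and no limit on the ratio was applied, unlike in the deposited tables. The list percentiles as used here were therefore not tested. In the simulated leaf comparison of 1183 genes the intervals covered the true fold for 96.0% of genes and excluded 1 for 88.0% of 2-fold and 99.0% of 4-fold changes. In the simulated root comparison of 4747 genes they covered 95.8% and excluded 1 for 90.0% of 2-fold and 100.0% of 4-fold changes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.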

Results

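Gene expression was measured by RNA sequencing in leaves and roots of Cavendish banana seedlings grown for 60 days with normal or low potassium. The design holds 4 samples, 1 library for each tissue and potassium supply, with between 4203693 and 4555265 fragments assigned to genes per library, as computed from the deposited values. The question behind the series is how leaf and root transcripts differ under low potassium. No comparison has a replicate check, so each fold given here compares 2 libraries and its 95% interval covers counting error only. Pairs of FPKM values are in the order normal, then low potassium. The authors' deposited table for leaf lists 1183 genes, of which 797 were higher and 386 lower in low potassium. The authors' deposited table for root lists 4747 genes, of which 1917 were higher and 2830 lower, so the root table is 4.01 times as long. The listed genes held 4.53% of the fragments in normal-potassium leaf and 6.34% in low-potassium leaf. In root they held 26.5% and 26.6%.

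The first comparison concerns potassium uptake and its regulation. Among the 31 genes the authors chose as related to potassium transport, the gene for potassium transporter 1 (Ma05_g07130), a member of the KUP/HAK family of potassium carriers, was the 1 gene listed in both tissues. It was 12.4-fold higher in low-potassium leaf (1.66 and 20.7 FPKM, interval 7.57 to 21.8) and 7.38-fold higher in low-potassium root (0.37 and 2.73 FPKM, interval 2.53 to 29.3). In root, 9 of the 14 CBL-interacting protein kinases were listed as higher, 1 was listed as lower and 4 were not listed. These kinases act with calcineurin B-like calcium sensors, and CIPK23 of Arabidopsis activates the potassium channel AKT1. Of the 14 in leaf, 3 were listed as higher, 1 as lower and 10 were not listed. Each of the 31 genes is listed in at least 1 tissue, so a kinase not listed in one tissue is listed in the other. The totals of kinases, transporters and channels given here are therefore not the sizes of whole gene families.

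The listed root kinases included CBL-interacting protein kinase 23 (Ma04_g29510), which measured 24.9 and 74.6 FPKM, 2.99-fold higher (interval 2.46 to 3.65). In leaf the same gene was at 3.88 and 3.97 FPKM. CBL-interacting protein kinase 2 (Ma07_g23630) was 4.40-fold higher in root (51.8 and 228 FPKM, interval 3.88 to 5.002), and CBL-interacting protein kinase 6 (Ma07_g29120) was 2.73-fold higher (91.3 and 249 FPKM, interval 2.47 to 3.03). The other kinases listed as higher in root, by 2.28-fold to 5.08-fold, were kinase 1 (Ma01_g17400, Ma08_g10700 and Ma03_g14540), kinase 12 (Ma06_g28510), kinase 19 (Ma04_g15200) and kinase 29 (Ma06_g34240). The kinase listed as lower in root, CBL-interacting protein kinase 7 (Ma06_g26140), had 4.41 FPKM in normal potassium and no fragment in low potassium. Against the floor of 3 counts it was 8.21-fold lower, with the 26 fragments in normal potassium taken as exact. In leaf, kinase 1 (Ma07_g17570), kinase 6 (Ma07_g05310) and kinase 11 (Ma09_g04710) were 3.05-fold, 2.57-fold and 2.21-fold higher, and kinase 1 (Ma11_g04530) was 2.09-fold lower. A kinase not listed in a tissue may still differ there. In leaf, the unlisted Ma07_g23630, Ma01_g17400 and Ma07_g29120 were 1.965-fold, 1.84-fold and 1.58-fold higher. The unlisted Ma08_g10700 and Ma03_g14540 were each 1.65-fold lower in leaf, and all of these intervals exclude 1. In root, the unlisted Ma09_g04710 and Ma07_g17570 were 1.98-fold and 4.71-fold higher (intervals 1.81 to 2.16 and 1.57 to 19.3). Kinase numbers are those of the potassium table, and the tissue tables name some of these genes by other numbers. Of the 8 potassium transporters of the KUP/HAK type, root listed 2 as higher and 4 as lower, and leaf listed 2 as higher and 1 as lower. Potassium transporter 6-like has copies of opposite direction in root. Ma07_g21520 was 4.41-fold higher (6.71 and 29.6 FPKM, interval 3.38 to 5.82), while Ma03_g06090 was 5.79-fold lower (5.79 and 1.0 FPKM, interval 2.94 to 12.7). Potassium transporter 17 (Ma07_g12190) was 4.48-fold lower in root (interval 2.55 to 8.42), and transporter 7-like (Ma09_g11150) and transporter 11 (Ma11_g16690) were 2.16-fold and 2.13-fold lower. In leaf, transporter 11 (Ma02_g04540) was 2.34-fold higher and transporter 13 (Ma03_g24780) 6.05-fold lower (interval 2.09 to 23.9). Though not listed in leaf, Ma11_g16690, Ma03_g06090 and Ma09_g11150 were 1.78-fold, 1.66-fold and 1.30-fold lower there, as in root. Unlike in leaf, Ma02_g04540 was 1.85-fold lower in root, where it is not listed. The intervals of these folds exclude 1.

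Of the 6 potassium channels, 2 were higher and 2 lower in root, and 1 was higher and 1 lower in leaf. The channel KOR1-like (Ma08_g23650) was 4.78-fold higher in root (1.65 and 7.88 FPKM, interval 2.90 to 8.62). KAT4-like (Ma05_g09470) was 2.65-fold higher in root (22.3 and 59.2 FPKM, interval 2.24 to 3.14). The abundant channel subunit beta gene (Ma09_g24000) was 2.29-fold lower in root (163 and 71.2 FPKM, interval 1.997 to 2.64), and KAT2-like (Ma06_g28610) was 2.28-fold lower. In leaf, KAT3-like Ma10_g27850 was 16.1-fold higher from a very low level (0.20 and 3.22 FPKM, interval 3.89 to 133) and KAT3-like Ma07_g09180 was 3.36-fold lower (interval 2.10 to 5.42). The counts of both KAT3-like genes are not whole, so these values are uncertain. The fold of Ma07_g09180 rests on its FPKM values (9.30 and 2.77), which fell more than its counts (74.08 and 25.79). The table also holds an expansin, Ma04_g21520, a cell wall protein that was 5.73-fold lower in root and is listed at 0 in both leaf libraries. Its cation/calcium exchangers were 5.41-fold higher in leaf (Ma08_g20660) and 2.17-fold lower in root (Ma05_g18280). The counts of 7 higher and 3 lower genes in leaf and 13 higher and 9 lower genes in root describe a list chosen on these samples, which is not independent evidence of its direction. With a pseudocount of 1 only 5 of the genes lower in root kept an absolute log2 ratio of 1 or more.

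**Figure D1:**
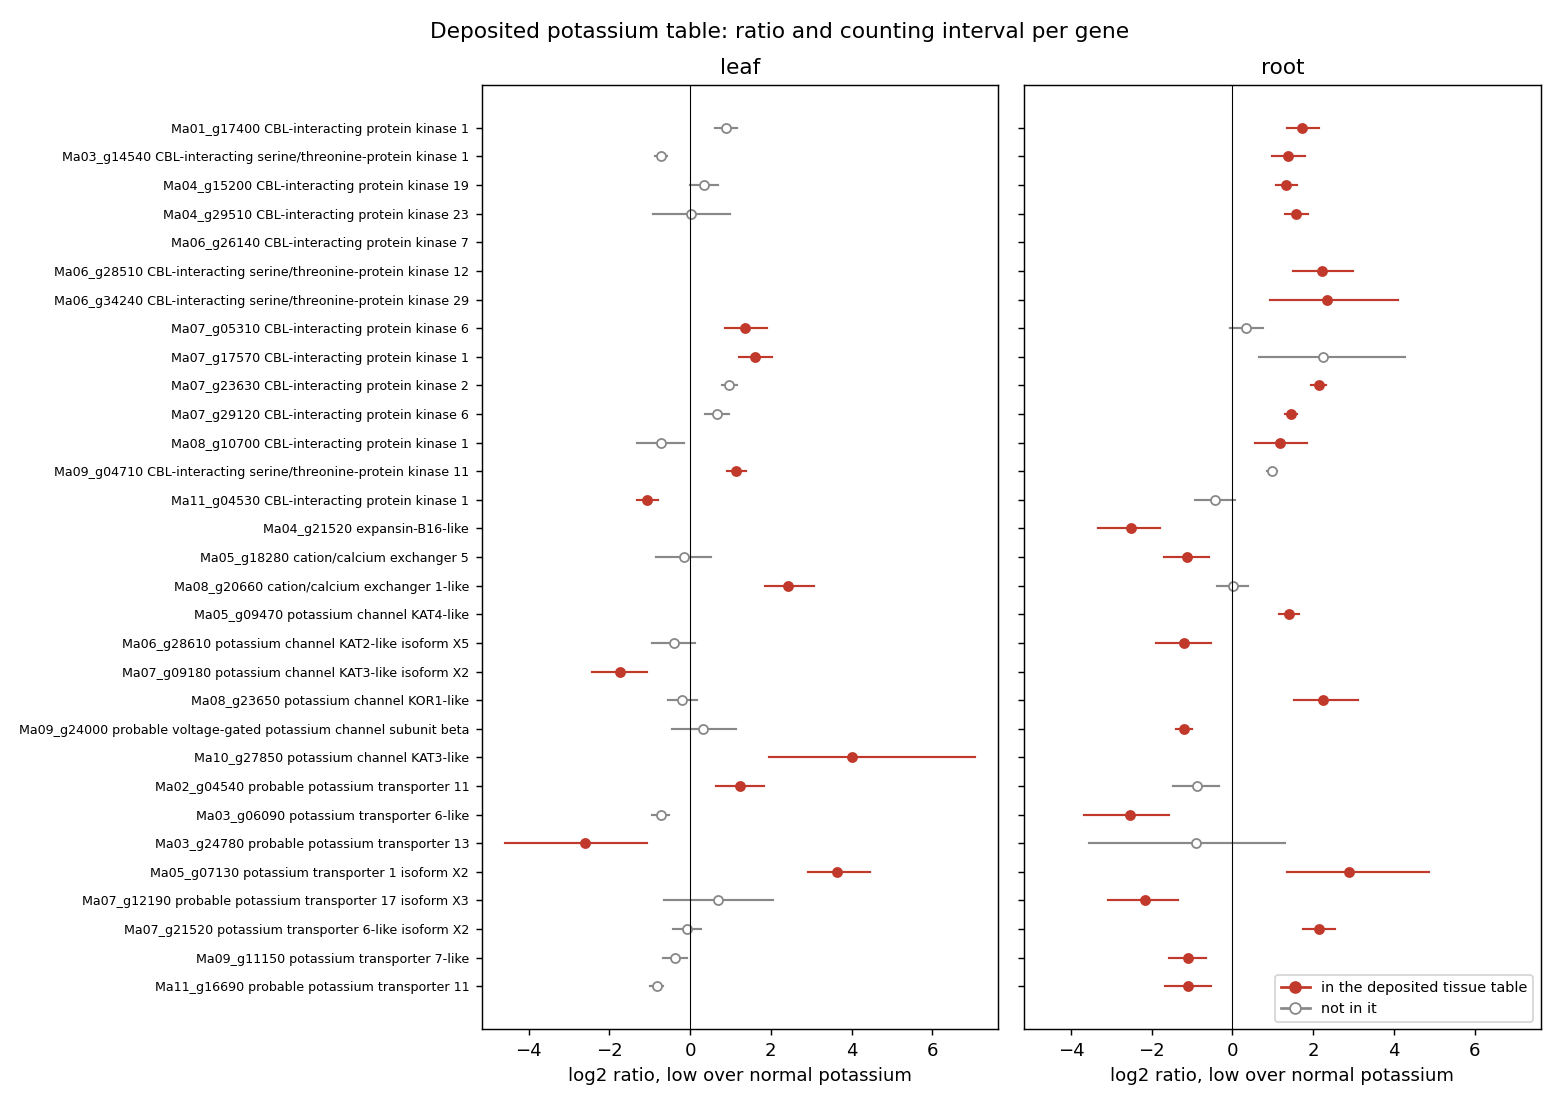
Log2 ratio of low over normal potassium (horizontal axis) for each of the 31 genes of the deposited potassium table in leaf and root, with 95% counting intervals as lines and no replicate error. Filled points are genes in the authors' deposited table of that tissue (10 in leaf, 22 in root), open points are not in it, and genes without a fragment in a library have no point.

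In leaf, among named genes of at least median FPKM, those with the largest ratios in low potassium included a NAC factor, TIFY proteins and an ethylene-responsive factor. The NAC domain protein 100-like gene (Ma10_g04910) measured 0.73 and 46.5 FPKM, 63.7-fold higher (interval 21.5 to 312). TIFY 5A-like (Ma04_g38060), of the family of jasmonate-response repressors, measured 0.55 and 32.3 FPKM (58.7-fold higher, interval 10.1 to 2358 from 1 fragment in normal potassium). TIFY 10B-like (Ma08_g18660) was 20.7-fold higher (interval 11.3 to 42) and the ethylene-responsive factor ERF109-like (Ma10_g30050) 30.9-fold higher (interval 10.2 to 152). A putative methyltransferase (Ma02_g01130) was 35.6-fold higher, and 2 phylloplanin-like genes (Ma08_g10050 and Ma05_g23730) were 25.1-fold and 21.0-fold higher. The most abundant higher genes were dehydrin COR410 (Ma11_g01190), a protective protein of water stress, at 476 and 2024 FPKM (4.25-fold, interval 4.01 to 4.51), and an 18.1 kDa class I heat shock protein (Ma01_g14490), 3.14-fold higher (interval 2.91 to 3.39).

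The genes lower in leaf included a nitrate transporter and a nitrate reductase. The high affinity nitrate transporter 2.5-like gene (Ma01_g16930) measured 256 and 23.4 FPKM, 10.96-fold lower (interval 9.18 to 13.2). A nitrate reductase gene (Ma09_g14900), the enzyme that reduces nitrate to nitrite, measured 1052 and 498 FPKM, 2.11-fold lower (interval 2.04 to 2.18). Among named genes of at least median level, SRG1-like (Ma11_g05490) had the largest ratio, 21.5-fold lower (interval 12.4 to 40.9). Phosphoenolpyruvate carboxylase kinase 2-like (Ma04_g18750) was 12.1-fold lower (interval 6.59 to 25.0). The ubiquitin ligase RING1-like (Ma05_g07430), the LRR receptor-like kinase Ma02_g18240 and cytochrome P450 78A4-like (Ma06_g22120) were 10.7-fold, 9.53-fold and 6.96-fold lower. The clock component LUX-like (Ma03_g22000) was 5.54-fold lower (interval 3.87 to 8.13). GDP-L-galactose phosphorylase (Ma10_g11130), an enzyme of ascorbate synthesis, measured 1659 and 822 FPKM, 2.02-fold lower (interval 1.95 to 2.09).

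Jasmonate genes, from a list fixed beforehand as were all groups named here, were higher for 26 of 28 listed members, with a median log2 ratio of 2.54 that lay at percentile 100 of the random lists. The most abundant were the 9S-lipoxygenases Ma06_g26850 (169.6 and 719.7 FPKM, 4.24-fold) and Ma06_g26840 (73.7 and 486 FPKM, 6.59-fold). There are 7 such enzymes in the list, and they oxidise fatty acids at another carbon than the 13S-lipoxygenases that start jasmonate synthesis. Cell wall genes were higher for 26 of 27 (median 1.81, percentile 96.7), among them a xyloglucan endotransglucosylase (Ma03_g05070) at 78.1 and 195 FPKM. All 14 NAC factors, all 12 other redox enzymes, all 9 photosynthesis genes and all 4 peroxidases were higher. Their medians lay at percentiles 88.8, 92.7, 73.4 and 94.0. Redox examples were catalase isozyme A (Ma01_g10810), 301 and 695 FPKM, and glutathione S-transferase U18-like (Ma05_g10090), 185 and 803 FPKM. Receptor-like kinases were mostly lower, with 16 higher and 64 lower (median -1.95, percentile 0), for example the LRR receptor-like kinase Ma07_g26520 at 259.7 and 107 FPKM. Nitrate, ammonium and phosphate transport had 10 higher and 13 lower (median -1.08, percentile 0.975, or 3.97 when also matched on length), and bHLH factors 3 higher and 4 lower (median -1.40, percentile 1.68).

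Like the cell wall, NAC, redox, photosynthesis and peroxidase medians, those of the lists below lay inside the middle 95% of the random lists, except cytochrome P450 (97.6) when also matched on length. Listed genes were 9 higher and 2 lower for calcium signalling, 16 and 3 for ethylene, 13 and 3 for abscisic acid and gibberellin, 15 and 5 for WRKY factors, 13 and 4 for cytochrome P450, 7 and 1 for sugar transport and sucrose cleavage and 10 and 2 for defence proteins. They were 9 and 5 for lignin and phenylpropanoid, 8 and 6 for MYB factors, 5 and 2 for heat shock proteins, 4 and 1 for cytokinin (the lower gene is the clock regulator PRR95, Ma09_g24730), 4 and 1 for ABC transporters, 5 and 4 for auxin, 3 and 3 for potassium transport and 2 and 5 for histones and cell division. The last list includes histone H3.v1-like (Ma05_g28720) at 101 and 48.9 FPKM, but also a calcyclin-binding protein (Ma06_g28590), which is not a cyclin. Aquaporins (1 and 1), ribosomal proteins (2 and 0), proton pumps (0 and 1) and other cation transport (0 and 1) had fewer than 3 listed members. These counts have no replicate check. The auxin median turned from 1.11 to -1.08 when genes under the median FPKM were left out.

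**Figure D2:**
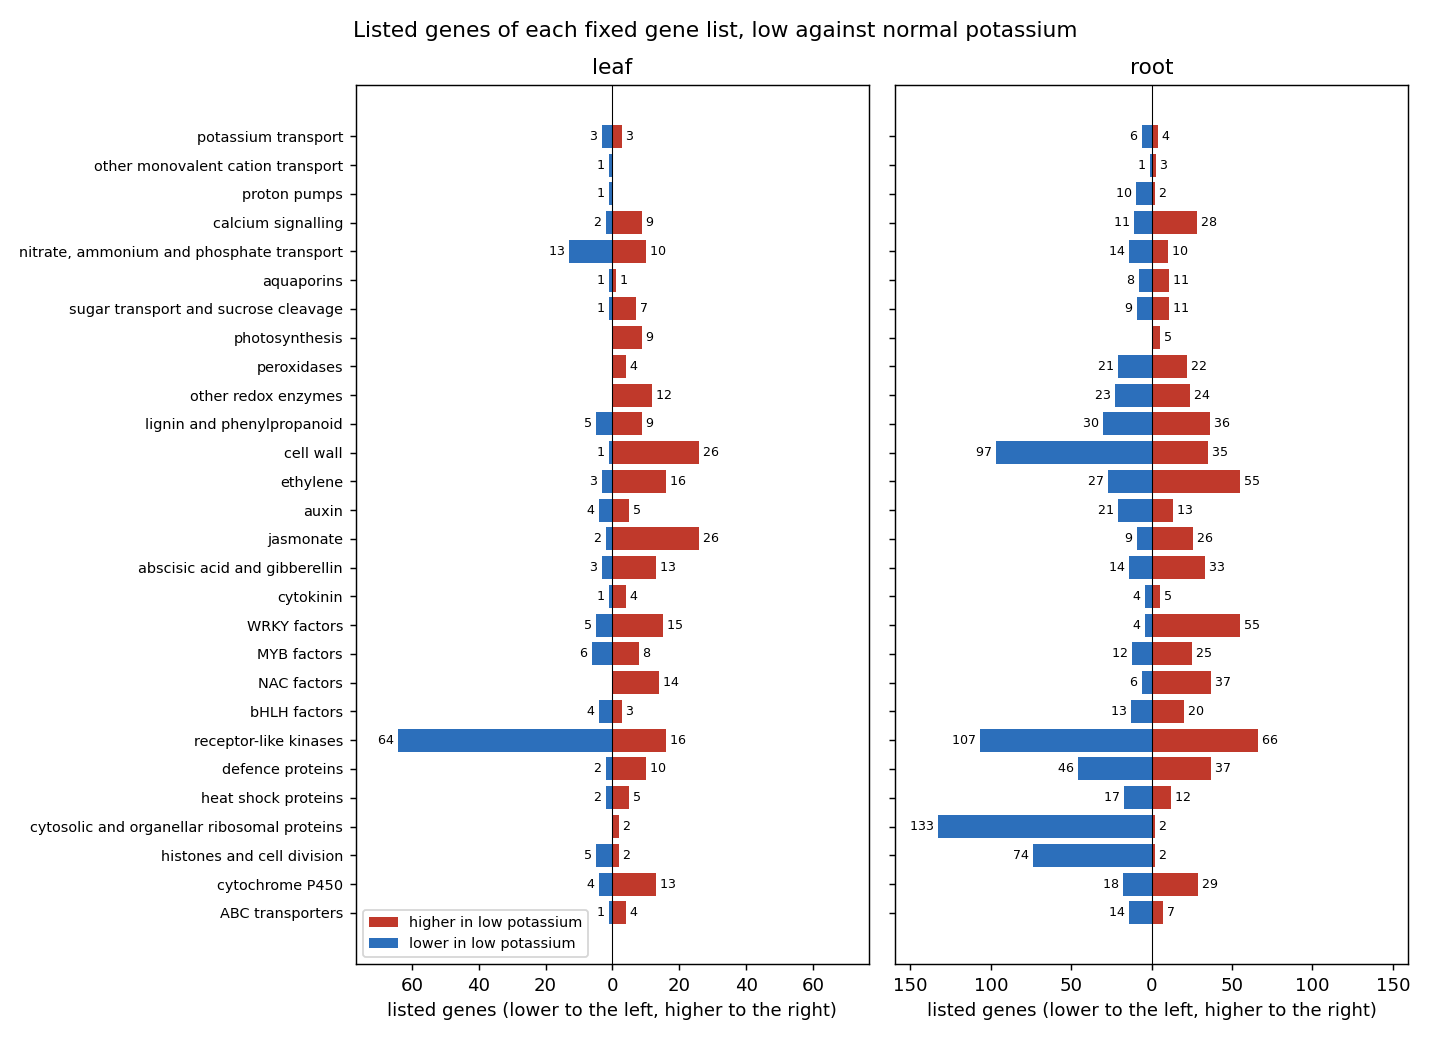
Number of listed genes (horizontal axis) that were higher (red, to the right) or lower (blue, to the left) in low potassium, for each of the 28 fixed gene lists in leaf and root, on separate scales. Ribosomal proteins were 2 higher and 133 lower in root, and cell wall genes were 26 higher and 1 lower in leaf against 35 higher and 97 lower in root.

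In root, the most abundant transcripts that were higher in low potassium were those of a metal-binding metallothionein, a water channel and a germin-like protein. Metallothionein-like protein 2A (Ma01_g10480) measured 3399 and 16295 FPKM, 4.79-fold higher (interval 4.61 to 4.99). The plasma membrane aquaporin PIP1-2 (Ma07_g18280) measured 1849.9 and 9765 FPKM, 5.28-fold higher (interval 5.14 to 5.42), and the germin-like protein 2-1 gene (Ma05_g29070) 1758 and 8331 FPKM, 4.74-fold higher. Among named genes of at least median level, the largest ratio was that of a horcolin-like gene (Ma09_g10350), named after a lectin, 79.4-fold higher (7.26 and 576 FPKM, interval 46.2 to 149.7). Nudix hydrolase 21 (Ma09_g27840) was 45.9-fold higher (interval 12.3 to 385). WRKY40 (Ma07_g16310) was 37.9-fold higher (interval 18.1 to 95.3), the zinc finger gene ZAT8-like (Ma06_g36260) 37.3-fold (interval 14.2 to 139), and WRKY70 (Ma06_g17380) 29.5-fold (interval 12.4 to 92.4). The calcium-binding KIC-like gene (Ma07_g28960) was 35.5-fold higher, from 2 fragments in normal potassium (interval 9.45 to 299). DREB1G (Ma08_g11720), of a family of cold and drought response factors, and the chaperone dnaJ 8 (Ma03_g13130) were 34.1-fold and 32.1-fold higher.

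Among named genes of at least median FPKM, those with the largest ratios among the genes lower in root included a cell wall invertase-type beta-fructofuranosidase (Ma06_g14700), which measured 49.2 and 1.07 FPKM, 46.0-fold lower (interval 22.9 to 106). The nitrate transporter 2.5-like gene (Ma01_g16930), also lower in leaf, measured 89.6 and 2.04 FPKM, 43.9-fold lower (interval 24.9 to 85.5). The factor ILI6-like (Ma02_g16690) and a phenolic glucoside malonyltransferase (Ma04_g23010) were 39.7-fold and 36.7-fold lower. Laccase-22-like (Ma11_g22550), of a family that oxidises lignin precursors, was 32.5-fold lower (interval 21.1 to 52.8). A cold-induced plasma membrane protein (Ma08_g15280) and a Bowman-Birk proteinase inhibitor (Ma04_g24990) were 26.9-fold and 24.6-fold lower. An ACC oxidase gene (Ma05_g09360), which makes the last step of ethylene synthesis, was 23.2-fold lower (interval 16.3 to 34.1). The most abundant lower transcripts were mannose/glucose-specific lectins (Ma09_g10440, 6270.1 and 966 FPKM, 6.49-fold lower, and Ma09_g10460, 5.19-fold lower) and a Bowman-Birk inhibitor (Ma05_g10670, 3440.4 and 375 FPKM, 9.17-fold lower). The counts of these 3 and other named genes are not whole, as happens where fragments are shared among similar copies, so their values are uncertain.

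Genes of ribosomes and cell division were nearly all lower in root. Ribosomal protein genes were lower for 133 of 135 listed members, with a median log2 ratio of -1.26 at percentile 0. Examples were ubiquitin-40S ribosomal protein S27a (Ma01_g17420), at 599.9 and 258 FPKM, and 40S ribosomal protein S16-like (Ma03_g01510), at 552 and 275 FPKM. Histone and cell division genes were lower for 74 of 76 (median -1.87, percentile 0.93), for example histone H2B.11 (Ma10_g22780) at 216 and 93.4 FPKM. Cell wall genes were lower for 97 of 132 (median -1.89, percentile 0), among them an extensin-like protein (Ma06_g27060) at 796 and 305 FPKM and fasciclin-like arabinogalactan protein 7 (Ma03_g10710) at 812 and 240.5 FPKM. Beside these groups, all 5 listed photosynthesis genes, which also mark green tissue, were higher in low-potassium root (percentile 96.2), with the oxygen-evolving enhancer protein 1 gene (Ma08_g03860) at 10.2 and 48.1 FPKM.

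WRKY, NAC, MYB, ethylene and jasmonate genes were mostly higher in root. WRKY factors were higher for 55 of 59 (median 2.13), NAC factors for 37 of 43 (median 1.71) and ethylene genes for 55 of 82 (median 1.58), each at percentile 100. Jasmonate genes were higher for 26 of 35 (median 1.84, percentile 99.99), MYB factors for 25 of 37 (percentile 99.95), calcium signalling genes for 28 of 39 (percentile 99.8) and cytochrome P450 genes for 29 of 47 (percentile 99.7). The calcium signalling list takes in CBL-interacting kinases, and all 14 kinases of the potassium table are in the fixed lists. Its count is therefore not separate from the kinase counts given above. Examples were WRKY38 (Ma05_g07250), 115 and 648 FPKM, TIFY 10A-like (Ma06_g32750), 99.3 and 861 FPKM, and the calcium-binding protein PBP1-like (Ma03_g24180), 188 and 849 FPKM. Lignin and phenylpropanoid genes were 36 higher and 30 lower, bHLH factors 20 and 13, and abscisic acid and gibberellin genes 33 and 14, with medians at percentiles 99.1, 99.1 and 97.7. When also matched on length, the bHLH median lay at percentile 97.4, inside the middle 95%. The intervals of the medians include 0 for phenylpropanoid (-1.19 to 1.54), bHLH (-1.09 to 1.57) and cytochrome P450 genes (-1.13 to 1.58). Since 40.4% of all listed root genes were higher, a list split nearly evenly can already lie high among the random lists. The most abundant higher phenylpropanoid genes were 4-coumarate-CoA ligase-like 10 genes, Ma07_g18310 at 474.5 and 1477 FPKM and Ma09_g20540 at 187 and 1129 FPKM.

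Transport genes in root were found in both directions. Aquaporins were 11 higher and 8 lower, sugar transport and sucrose cleavage genes 11 and 9, nitrate, ammonium and phosphate transporters 10 and 14, potassium transport genes 4 and 6, other cation transport genes 3 and 1, and ABC transporters 7 and 14. Proton pumps were 2 higher and 10 lower, the lower ones being vacuolar, such as V-type ATPase subunit A (Ma01_g01200), 2.12-fold lower, and the pyrophosphate-energized pump Ma03_g12920, 3.08-fold lower. Auxin genes were 13 higher and 21 lower, with IAA30-like (Ma04_g27630) at 180.3 and 50.5 FPKM and auxin efflux carrier 2 (Ma01_g09070) at 152 and 13.8 FPKM. Receptor-like kinases were 66 higher and 107 lower, defence proteins 37 and 46, heat shock proteins 12 and 17, peroxidases 22 and 21, other redox enzymes 24 and 23, and cytokinin genes 5 and 4, with the clock regulator PRR1 (Ma02_g06530) counted as higher. The medians of the nitrate, sugar, peroxidase, auxin, cytokinin, receptor-like kinase, defence and heat shock lists changed sign when genes under the median FPKM were left out.

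The last comparison asks whether leaf and root listed the same genes. The tables share 410 genes, which is 34.7% of the leaf table and 8.64% of the root table. Of these, 266 were higher in both, 33 were lower in both, 81 were higher in leaf and lower in root, and 30 were lower in leaf and higher in root. The same direction was thus seen for 72.9% (95% exact binomial interval 68.3% to 77.2%, with genes counted as if independent). This share was 76.7% for the 347 shared genes higher in leaf but 52.4% for the 63 lower in leaf. Independent lists would share at most 71.1 genes higher in both, 50.8 lower in both, 105 higher in leaf and lower in root, and 34.4 lower in leaf and higher in root, given at least 21486 genes tested in leaf. With 30160 genes these expectations are 50.7, 36.2, 74.8 and 24.5. The count higher in both lies above either value. The count lower in both lies under either value, though these are upper limits. The counts of opposite direction lie between their expectations. The comparisons share no library, but abundant genes pass limits based on counts more readily in both tissues, which independent lists leave out.

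Ranked by the smaller of their 2 ratios, the 4 named genes that changed most in the same direction in both tissues were higher. TIFY 5A-like (Ma04_g38060) was 22.9-fold higher in root (14.1 and 322 FPKM, interval 15.5 to 34.98), beside its higher level in leaf. A further TIFY 5A-like gene (Ma06_g32910) was 18.2-fold higher in leaf and 28.1-fold higher in root. The bHLH92-like factor (Ma03_g30510) was 45.4-fold higher in leaf (interval 12.2 to 381) and 20.6-fold higher in root (interval 15.8 to 27.3), and the stem-specific protein TSJT1-like gene (Ma10_g07930) was 21.4-fold and 21.0-fold higher. Among genes of opposite direction, a mannose-specific lectin (Ma06_g16670) was 8.12-fold higher in leaf (25.2 and 205 FPKM) and 10.04-fold lower in root (499 and 49.8 FPKM). The LRR receptor-like kinase Ma02_g18260 was 12.8-fold lower in leaf (interval 3.61 to 123.4) and 9.75-fold higher in root (interval 8.03 to 12.02). Its counts are not whole, so these values are uncertain.

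**Figure D3:**
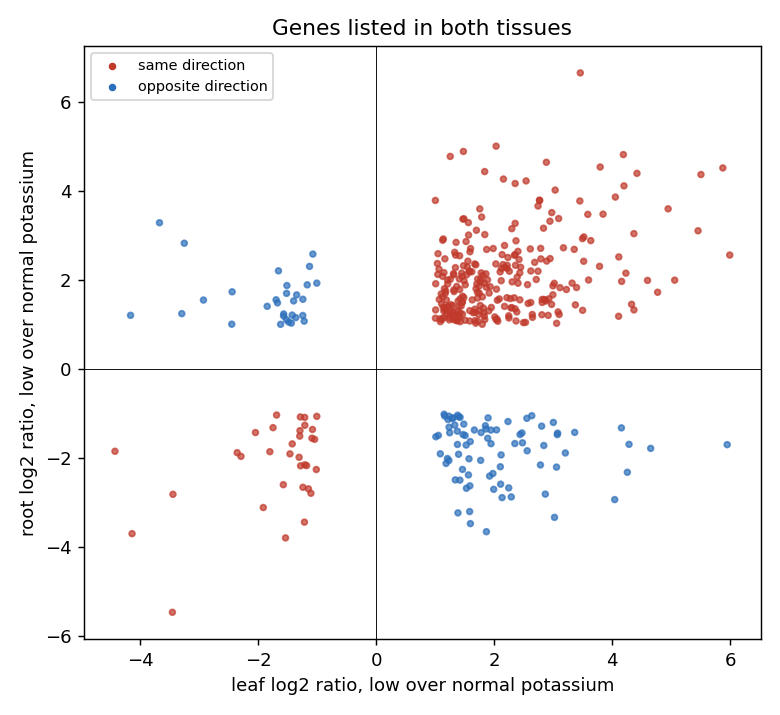
Log2 ratio of low over normal potassium in root (vertical axis) against leaf (horizontal axis) for the 410 genes in both deposited tables, 1 point per gene, with genes at 0 in a library placed at the 3-count floor. Red points (299 genes) have the same direction in both tissues and blue points (111 genes) opposite directions, and the gap around 0 is the authors' log2 limit of 1.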

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

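The results below had opposite directions in leaf and root. The difference between the tissues was not tested, since each rests on 1 library per condition, and no explanation was tested for any of them.

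As log2 ratios of low over normal potassium in leaf minus root, the differences were -6.96 for the LRR receptor-like kinase Ma02_g18260 (-3.67 in leaf and 3.29 in root), -6.08 for the LRR receptor-like kinase Ma02_g18240 (-3.25 and 2.83), 6.97 for the receptor kinase TMK1 gene Ma08_g31260 (4.04 and -2.93), and 6.35 for the mannose-specific lectin Ma06_g16670 (3.02 and -3.33). The counts of Ma02_g18260 and Ma02_g18240 in both tissues and of Ma08_g31260 in root are not all whole, as happens where fragments are shared between similar genes or transcripts, so these values are uncertain.

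In the potassium table the differences were 2.11 for potassium transporter 11 (Ma02_g04540, 1.23 in leaf and -0.89 in root), -2.10 for CBL-interacting protein kinase 1 (Ma03_g14540, -0.72 and 1.39) and -1.91 for CBL-interacting protein kinase 1 (Ma08_g10700, -0.72 and 1.19). In each of these 3 the counting intervals excluded 0 in both tissues, while only 1 of the 2 tissue tables lists the gene. The leaf counts of Ma02_g04540 are not whole either.

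For whole lists, the medians differed by 3.70 for cell wall genes (1.81 in leaf and -1.89 in root), 3.09 for ABC transporters (1.60 and -1.50), 2.55 for auxin (1.11 and -1.44), 2.51 for heat shock proteins (1.46 and -1.05), 2.39 for defence proteins (1.23 and -1.16) and -2.63 for bHLH factors (-1.40 and 1.23). Since 67.4% of listed leaf genes and 40.4% of listed root genes were higher, random lists also tend to opposite signs. In leaf and root the medians lay inside the middle 95% of the random lists for ABC transporters (percentiles 55.4 and 41.2), auxin (21.6 and 2.82), heat shock proteins (70.2 and 70.4) and defence proteins (32.5 and 71.6). The intervals of the medians include 0 in both tissues for ABC transporters, auxin, heat shock proteins and bHLH factors, and in root for defence proteins. The auxin median in leaf and the auxin, heat shock and defence medians in root change sign with the filter on low values.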

How the results depend on the processing

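With 1 library per group no replicate could be left out. No paired analysis was possible within a tissue because its groups have 1 sample each, and a fit with tissue as the block was not run. Scaling to the total of unlisted genes and the genes left out for counts that are not whole were chosen after seeing the data, as was the 3-count floor. Requiring an absolute log2 ratio of 2 left 313 higher and 99 lower genes in leaf (76.0% higher) and 692 and 1159 in root (37.4% higher), and 84 genes in both tissues, 84.5% in the same direction. Leaving out genes under the table's median FPKM left 404 and 188 in leaf, 1149 and 1225 in root (48.4% higher, against 40.4% in the full table) and 185 genes in both tissues. Leaving out genes with a count that is not whole left 480 and 224 in leaf and 1164 and 1514 in root (43.5% higher). These alternatives lower the counts by construction, and neither tissue changed its majority direction. With a pseudocount of 1, 5 potassium table genes were lower in root instead of 9. Of the recomputed list medians, 241 kept their sign within the interval of the full list and 4 left it with the same sign. With the median FPKM filter 9 changed sign: auxin in leaf (-1.08), and in root nitrate, ammonium and phosphate transport (0.05), sugar transport and sucrose cleavage (-1.04), peroxidases (-1.28), auxin (1.07), cytokinin (-1.05), receptor-like kinases (1.35), defence proteins (1.13) and heat shock proteins (1.05). The intervals of the full lists include 0 for each of these except receptor-like kinases. The log2 ratio of the share of unlisted genes was -0.03 in leaf and -0.0006 in root, and scaling to that share raises each log2 ratio by as much. Depth limits genes of low level, where folds of named genes with 1 to 3 fragments in a library have wide intervals.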

Other observations

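The gene groups and genes named here, except the ribosomal protein and cell division lists, were chosen after values had been seen, as were the tests given with them, except those of gene length and of a single scaling factor. In low-potassium root, genes of glycolysis and the cytoskeleton were lower together. Tubulins and actins were lower for 27 of 28 listed genes (median log2 ratio -2.05, percentile 0), for example tubulin alpha-2 (Ma02_g19010) at 1004 and 157 FPKM. Glycolytic and fermentative enzymes were lower for 22 of 23 (median -1.60, percentile 1.31), among them cytosolic aldolase (Ma08_g01140) at 2757 and 989 FPKM and a glyceraldehyde-3-phosphate dehydrogenase (Ma11_g17540) at 2523 and 1092 FPKM. All 12 translation factors were lower (percentile 36.5), including elongation factor 1-alpha (Ma03_g18930) at 1495 and 686 FPKM. In leaf, the 2 listed tubulins and the 1 translation factor were higher. The 2 genes of the glycolysis and fermentation group listed in leaf were also higher. These were the fermentation enzymes pyruvate decarboxylase 2 (Ma05_g07150) and alcohol dehydrogenase (Ma08_g29910), so leaf gives no direction for glycolysis itself.

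Lectins and proteinase inhibitors had mostly opposite directions in the tissues. Lectins of the jacalin and mannose-binding families were higher for 5 of 5 in leaf and lower for 7 of 9 in root (percentiles 98.7 and 0.01, in leaf 97.4 when also matched on length). The lectin Ma09_g10470 measured 34.1 and 283 FPKM in leaf and 2652 and 577 FPKM in root. Proteinase inhibitors were higher for 8 of 8 in leaf and lower for 7 of 10 in root (percentiles 99.7 and 0.05, in leaf 97.3 when also matched on length), and the Bowman-Birk gene Ma04_g24980 measured 48.1 and 406 FPKM in leaf and 1481 and 547 FPKM in root. The intervals of the root medians include 0 for lectins (-2.94 to 4.81) and for proteinase inhibitors (-3.37 to 3.04), since some members were much higher there. Nitrogen assimilation genes were lower for 6 of 7 in leaf (percentile 0.53) and 3 of 5 in root (58.7), while asparagine synthetase (Ma05_g30550) was 7.38-fold higher in leaf and 24.97-fold higher in root. This group also counts NLP1-like (Ma03_g15290) and NLP2-like (Ma02_g02550), both lower in leaf, and an NLP3 gene (Ma03_g26430) in root, which are not assimilation enzymes. Late embryogenesis proteins and dehydrins were higher for 3 of 3 in leaf and 4 of 5 in root (percentiles 90.8 and 85.3), and both listed metallothioneins were higher in root.

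The lower ribosomal protein and cell division genes in low-potassium root were weighed against 3 explanations. If a few abundant genes had taken more of the fragments, the share of all other genes would fall, but outside the genes listed as higher it was 0.850 times that in normal potassium, against at most 0.434 needed for the ribosomal median, and unlisted genes as a whole gained no share. Since only genes past the log2 limit of 1 are listed, the needed share was bound to be low, and ribosomal genes with smaller changes are not seen. These values argue against this explanation only as the whole cause for the listed genes, and a partial contribution stays open. Gene length is argued against too, since both medians lay at or under percentile 0.13 of random lists matched on length and expression. A smaller share of growing root tip in the low-potassium sample may account for the pattern and stays open. The ribosomal, cell division and tubulin medians lay within 0.792 of each other. Since all listed genes lie past the log2 limit of 1, lists of mostly lower genes tend to lie close, so this decides nothing. The interval of the ribosomal median (-1.34 to -1.20) overlapped neither that of cell division (-2.12 to -1.67) nor that of tubulins and actins (-2.45 to -1.87). All 6 listed PLETHORA-type factors of growing tips were lower (percentile 35.1, inside the middle 95%). An effect of low potassium within the same cells would also lower these groups and was not tested.

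Clock genes that peak in the morning were lower in low-potassium leaf for 6 of 6 listed genes, such as PRR95 (Ma09_g24730) at 512 and 200.8 FPKM, and higher in low-potassium root for 9 of 9, such as LHY-like (Ma10_g07650) at 53.6 and 124 FPKM. Evening genes were 1 higher and 2 lower in leaf and 4 higher and 1 lower in root (percentiles 8.31 and 70.3). A shift of harvest hour shared by tissues in phase predicts the same direction in each, and the shares of higher genes were 100 percentage points apart, but no gene is in both lists and both medians lay inside the middle 95% of the random lists (percentiles 3.12 and 92.1), so it stays open. A difference in harvest hour between leaf and root alone cancels, since each ratio is taken within a tissue. Harvest hours that differed between low and normal potassium, in opposite senses in leaf and root, stay open. A tissue-specific effect of potassium supply stays open too. The smaller evening list had 3 members, too few to decide, and the labels give no hour.

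The root table lists about 4 times as many genes as the leaf table. Depth alone is argued against: after thinning to the leaf depths, 4307 root genes still passed the leaf limits of p and fold by an exact binomial count test, against 4407 before thinning. A single wrong scaling factor would act in 1 direction, but 692 root genes were higher by a log2 ratio of 2 or more and 1159 lower, each more than the 412 leaf genes in both directions together. Variation between plants or libraries stays open, since there is 1 library per tissue and potassium level, as does a larger effect of low potassium in root.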
